A study of Mus musculus with 5 samples.

How the data were processed

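Total RNA of 5 mouse cell cultures was labelled with the dye Hy5 and hybridised to single-colour microRNA (miRNA) arrays, 1 array per culture, per the labels. Per the file headers, the array design is version 19 of a mouse miRNA set. Each deposited file holds 1 array's scanner output: the intensity of each spot as the median brightness of its pixels, with no background taken off. The 5 arrays lay on 2 chips, with ZHBTc4 ES alone on the second, and the detector gain was 43 for the embryoid body, 46 for 2TS22c ES and 47 for the other 3 arrays. Each array had 1265 mouse miRNA spots with 1 spot per miRNA, 1664 blank spots, 24 negative control spots and 8 spots of each spike control. No spot was marked by the software as other than good, and none of the miRNA spots was saturated. A total of 13 spots stand for several miRNAs that share a probe; these are named with all their names joined by a slash. The miRNA names are those of the array design, and no genome build is named in the files, so no coordinates are given.

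The authors also deposited a table of processed intensity values, and neither the labels nor the files state how it was made. Set against the scanner values, each column followed a straight line (Pearson r of 0.99998 or more on each array) with a background level taken off, and each column's median was 25. These values are therefore linear, background-subtracted and scaled per array to a shared median; how the background was chosen stays unknown. A miRNA without a value in that table was set to the array's lowest value when the table was used as an alternative.

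The spot intensities were corrected with limma's normexp model (saddle-point fit on all spots, offset 50), quantile-normalized over the 1265 miRNA spots of the 5 arrays, and put on a log2 scale. The local brightness around the spots was left out of the main correction because it rose with the spot's own signal (Spearman rho across miRNAs from 0.559 to 0.775 per array); this choice was made after the values had been seen, and the correction with local background is one of the alternatives. The offset pulls the fold differences of dim miRNAs towards 1. A miRNA counted as detected on an array when its intensity lay above the mean plus 2 SD of the blank spots there, since the software's own marks do not separate spots. Between 2.82% and 4.15% of the blank spots lay above that limit. Where a miRNA was detected on 1 of the 2 arrays compared, the difference is given as a bound ("at least N-fold"), set against the higher of the dim spot's own signal and the lowest detected signal of that array.

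With 1 array per group, a comparison of 2 arrays has no replicate check and no test; it describes those arrays and not the conditions. For each of the 4 comparisons with V6.5 ES, the miRNAs at least 2-fold higher or lower among those detected on at least 1 of the 2 arrays were counted. The one test was limma (lmFit and eBayes, Benjamini-Hochberg adjusted p under 0.05) of the embryoid body against the 4 ES arrays, over the 959 miRNAs detected on at least 1 array. The 4 ES arrays are of different lines, so their spread includes line differences, and the single embryoid body is assumed to vary as they do. On simulated data with 959 miRNAs, 200 of them changed and each miRNA given its measured spread between the ES arrays, that test recovered 74.1% of 2-fold and 92.8% of 4-fold changes, with a mean of 6 and 7.65 false calls. With fewer changed miRNAs the adjusted threshold is stricter, and the simulated arrays were drawn independently. These shares therefore do not give the power of the test on the real arrays. The number of arrays limits the precision of every value.

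A set of 18 miRNA lists was fixed before the data were examined. They hold the miR-290-295, miR-302 and miR-367, miR-17-92 and paralogous, Dlk1-Dio3, Hox and miR-322 and miR-503 clusters; the let-7, miR-125 with miR-99/100, miR-200, miR-297, miR-466, miR-467 and miR-669, miR-15, miR-16, miR-195 and miR-497 and miR-34 families; miRNAs of heart and skeletal muscle, of neural tissue, of liver, gut and pancreas, of blood and endothelium, and of mesenchyme and fibroblasts (which also serve as markers of feeder cells); and miRNAs reported to act on pyruvate kinase M. For each list with 3 or more detected members, the median log2 difference is given with its percentile among 10000 random lists of the same size drawn from the same deciles of signal, as a description of the 2 arrays. The named miRNAs were chosen by a rule fixed at the same time: in each comparison the 12 with the largest positive and the 12 with the largest negative difference among those detected on both arrays, the 5 brightest detected on 1 array only in each direction, list members at least 2-fold apart, miR-369, and any miRNA past the limma threshold. Other miRNAs named are members of these lists given as examples, or are said to have been chosen after their values were seen.

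The alternatives chosen before the data were examined were an offset of 16, no background correction, scaling to the median of the 392 miRNAs detected on all 5 arrays, scaling to the 75th percentile, the authors' values, only miRNAs detected on both arrays, no filter, normalization of only the 2 arrays compared, and a detection limit of 3 SD; for the limma test, also leaving out each ES line and an intensity trend. Local background, scaling to the spike controls, a detection limit from the negative control spots, and PKM1 KI ES in place of V6.5 ES as the reference were added after seeing the data. Because all 4 comparisons share the V6.5 ES array, correlations between them are given beside 1000 simulated pairs of unchanged arrays that share one. The computations used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.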

Results

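The miRNA content of 4 mouse embryonic stem (ES) cell lines and of 1 embryoid body culture was measured on 5 arrays, 1 for each. V6.5 is a wild-type ES line. PKM1 KI ES carries, by its label, a knock-in of PKM1, the M1 form of the glycolytic enzyme pyruvate kinase. 2TS22c and ZHBTc4 are ES lines built for switching off Sox2 and Oct3/4, in which a drug ends expression of the factor; the labels name no drug or other treatment, nor feeder cells, for any culture. The ES cells grew with leukaemia inhibitory factor (LIF), which keeps mouse ES cells undifferentiated. The embryoid body (EB), a floating aggregate in which ES cells differentiate, was V6.5 kept without LIF for 1 week. The genes altered in these lines are not measured by a miRNA array, so the labels could not be checked on them. Values below are normalised log2 signals, with no replicates in any group.

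Of 1265 miRNA spots, 754 were detected on the V6.5 ES array, 763 on PKM1 KI ES, 750 on the EB, 507 on 2TS22c ES and 520 on ZHBTc4 ES. These are 59.6%, 60.3%, 59.3%, 40.1% and 41.1% of the spots. With the limit set on the negative control spots in place of the blank spots, the shares were 37.3%, 36.9%, 39.2%, 30.6% and 29.0%. The signal of all miRNAs together, over that of the spike controls, was 27.5, 30.6, 39.4, 21.1 and 22.9 in the same order. The spots of miR-3968, miR-5100, miR-6366 and miR-5097 were among the 6 brightest on each of the 5 arrays, and the 6 brightest took 42.6% to 58.0% of the miRNA signal. Among the clusters known from pluripotent cells, the miR-290-295 cluster, the main miRNA cluster of mouse ES cells, was detected with all 14 of its spots on V6.5 ES, with a log2 signal of 11.25 for miR-294-3p. The miR-302 and miR-367 cluster, which is known from the early post-implantation embryo and shares a seed sequence with much of the miR-290-295 cluster, was also detected, with 8.14 for miR-302d-3p; signals of different probes do not rank the miRNAs by amount.

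The arrays fell close together in some pairs and apart in others. Across the 392 miRNAs detected on all 5 arrays, which are not independent replicates, Pearson's r was 0.987 between V6.5 ES and PKM1 KI ES, 0.978 between V6.5 ES and the EB, and 0.988 between 2TS22c ES and ZHBTc4 ES. It was 0.928 between V6.5 ES and 2TS22c ES and 0.940 between V6.5 ES and ZHBTc4 ES. The miRNAs at least 2-fold apart numbered 3, 3, 1, 40 and 34 in these pairs in the same order, and 7 between PKM1 KI ES and the EB. PKM1 KI ES and the EB each differed from 2TS22c ES and ZHBTc4 ES by 54 to 65 miRNAs.

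**Figure D1:**
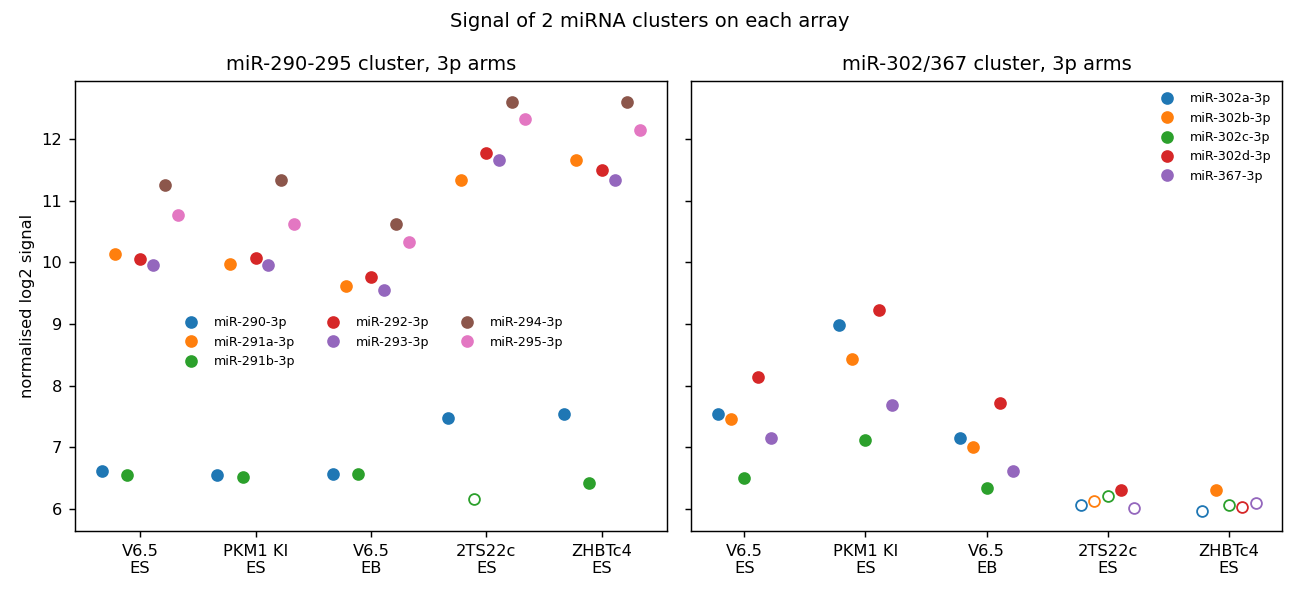
Normalised log2 signal (vertical axis) of the 3p arms of the miR-290-295 cluster (left) and the miR-302 and miR-367 cluster (right) on each of the 5 arrays (horizontal axis); each point is 1 spot on 1 array, filled where detected and open where not. miR-294-3p lies at 11.25 on V6.5 ES and at 12.61 on 2TS22c ES and ZHBTc4 ES, while miR-302a-3p lies at 7.54 on V6.5 ES, at 8.98 on PKM1 KI ES and below detection on 2TS22c ES and ZHBTc4 ES.

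The EB was compared with V6.5 ES to see how the miRNAs of the wild-type line differ after a week of differentiation. miRNAs known from differentiated cells lay on both sides: miR-124-3p, the main miRNA of neurons, was 1.84-fold higher on the EB array, and miR-29a-3p, abundant in fibroblasts and other differentiated cells, was the lowest, close to the detection limit there. The log2 signal of miR-124-3p was 7.52 on the EB, 6.64 on V6.5 ES and 6.16 on PKM1 KI ES. It was also above V6.5 ES in 2 other ES lines, at 7.26 on 2TS22c ES and 7.18 on ZHBTc4 ES. miR-9-5p, of neural progenitors, was detected on the EB array and not on V6.5 ES, at least 1.67-fold higher, but the neural list that holds it and miR-124-3p had 5 members higher and 6 lower, with a median of -0.04 (percentile 24.97). miR-99a-5p and miR-100-5p, which belong to a family that appears as ES cells differentiate, were likewise seen on the EB array only, each at least 1.44-fold higher. miR-290-295 members were slightly lower, with 13 of 14 below V6.5 ES and a median log2 difference of -0.26, at percentile 0.735 of the matched lists. Scaled to the spike controls, however, that median was 0.08, beside a shift of 0.22 for all miRNAs detected on both arrays.

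The largest EB difference was that of miR-711, 2.25-fold higher, the only miRNA at least 2-fold higher. miR-2137 was 1.93-fold, miR-301a-3p 1.81-fold, miR-181a-5p 1.65-fold and miR-107-3p 1.63-fold higher. The 2 miRNAs at least 2-fold lower were miR-669f-3p at 2.10-fold and miR-29a-3p. The EB spot of miR-29a-3p lay at the detection limit (raw intensity 41, limit 40.3) and below the limit from the negative control spots, with which 1 miRNA remained lower. miR-1949 was 1.99-fold lower in the main processing but higher by 0.36 on the log2 scale with local background correction. Among 850 miRNAs detected on either array there was no other difference of that size.

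By list, the miR-297, miR-466, miR-467 and miR-669 families, most of whose near-identical members lie in an intron of Sfmbt2, were lower as a group on the EB array: 53 of 60 detected members were below V6.5 ES, with a median of -0.33 below all matched lists, led by miR-669f-3p, miR-669f-5p (1.99-fold), miR-467a-3p (1.95-fold) and miR-466a-3p/miR-466e-3p (1.95-fold). Probes of such similar sequences can share signal, so single members are uncertain and the members are not independent readings. The matched lists were drawn without regard to such sharing. The percentile of this group can therefore overstate how far it stands out, here and in the comparisons below. The miR-125 and miR-99/100 families had a median of 0.38 (percentile 99.955), with 6 of 7 members higher, but only 0.05 with local background correction. The miR-302 and miR-367 cluster had a median of -0.27 (percentile 0.22), which was 0.12 with local background correction and -0.06 with spike scaling. The let-7 family, which accumulates late in differentiation, differed little, with a median of 0.08 over 13 members, and its sign turned with the authors' values (-0.14). The miR-17-92 and paralogous clusters lay at 0.05 (-0.17 with local background), the Dlk1-Dio3 imprinted cluster at -0.01 over 79 members (0.18 with spike scaling), and the miR-200 family of epithelial cells at 0.14. Medians of the lists of differentiated tissues were 0.16 for heart and skeletal muscle (-0.06 with local background), -0.04 for neural (0.12 with spike scaling, 0.11 with local background and 0.53 with the authors' values), -0.10 for liver, gut and pancreas (0.12 with spike scaling), 0.00 for blood and endothelium and 0.00 for mesenchyme and fibroblasts, with percentiles from 12.3 to 96.0. The Hox cluster miRNAs lay at 0.06 (-0.09 with local background), the miR-322 and miR-503 cluster at 0.09 (-0.06 with median scaling, -0.08 with the authors' values), the miR-15, miR-16, miR-195 and miR-497 family at 0.06, the miR-34 family at 0.01 (-0.17 with local background) and the miRNAs acting on pyruvate kinase M at 0.14.

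Against all 4 ES lines together, no miRNA passed the limma test in either direction among 959. The lowest adjusted p was 0.66, shared by miR-99a-5p, with a difference of 0.70 (SE 0.11), miR-9-5p at 0.73 (SE 0.13), miR-100-5p at 0.63 (SE 0.12), miR-6394 at 0.65 (SE 0.12) and miR-1949 at -0.93 (SE 0.16), and each of these 5 lay outside the range of the 4 ES arrays. At an unadjusted p under 0.05, 15 miRNAs were higher and 8 lower in the EB. That is a smaller share of the 959 than the 0.05 set for chance alone. Each of the ES arrays set in the EB's place also gave 0 limma calls in both directions. Unadjusted counts higher and lower were 34 and 1 for V6.5 ES and 10 and 8 for PKM1 KI ES. They were 59 and 32 for 2TS22c and 30 and 16 for ZHBTc4. In each swap the array's close partner (r of 0.987 or 0.988) stayed among the other 4, so differences shared by the pair widened their spread. The 0 calls therefore do not measure what chance would give.

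PKM1 KI ES was compared with V6.5 ES to ask which miRNAs differ in cells with the altered pyruvate kinase. The miR-302 and miR-367 cluster stood out. miR-302a-3p was 2.72-fold higher than on V6.5 ES, miR-302d-3p 2.13-fold, miR-302b-3p 1.96-fold, miR-302c-3p 1.53-fold and miR-367-3p 1.45-fold, and miR-302d-5p was detected on the PKM1 KI array only, at least 1.25-fold higher. All 8 detected members were higher, with a median of 0.59, above all matched lists, and miR-302a-3p and miR-302d-3p were the only 2 of 874 miRNAs at least 2-fold higher. The miR-290-295 cluster did not differ with it: its median was -0.02, with 6 members above and 7 below V6.5 ES, and 0.04 with spike scaling.

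The one miRNA at least 2-fold lower in PKM1 KI ES was miR-706, by 2.81-fold. Other miRNAs among the lowest were miR-199a-3p/miR-199b-3p, of mesenchymal cells, at 1.57-fold, miR-125b-5p, a miRNA of differentiated cells, at 1.54-fold, and members of the Sfmbt2 group, among them miR-297a-5p at 1.74-fold, miR-669a-3p/miR-669o-3p at 1.71-fold and miR-467a-3p at 1.69-fold. The miR-297, miR-466, miR-467 and miR-669 families were lower for 53 of 58 members, with a median of -0.29 below all matched lists. Mesenchymal and fibroblast miRNAs, which also mark feeder cells, had a median of -0.22 (percentile 0.04) with 11 of 14 lower, -0.14 with bounds, and 0.03 with local background correction. let-7 had a median of -0.15 (percentile 0.66), which was 0.02 with local background correction, and the miR-34 family one of -0.19 (percentile 1.105), or -0.10 with bounds. Other processings gave larger differences. Without bounds, medians ranged from -0.82 to 0.02 for let-7 and from -0.66 to -0.16 for miR-34. The mesenchymal and fibroblast median ranged from -0.67 to 0.03. The miR-125 and miR-99/100 families at -0.19 (percentile 1.89) and the miR-17-92 and paralogous clusters at -0.16 (percentile 0.22) were also slightly lower. The miR-322 and miR-503 cluster had a median of 0.15 (percentile 97.9), which was 0.08 with bounds and -0.01 with local background correction.

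The miRNAs reported to act on pyruvate kinase M had a median of -0.00 over 7 detected members in PKM1 KI ES, but -0.25 with the authors' values, -0.13 with local background and 0.03 with spike scaling. miR-369, fixed for naming beforehand because it is reported to act on the splicing of Pkm, lay close to the detection limit. miR-369-3p was detected on V6.5 ES only, at least 1.14-fold above PKM1 KI ES and at least 1.13-fold above the EB. miR-369-5p was detected on PKM1 KI ES and the EB only, at least 1.03-fold above V6.5 ES in both. Its raw intensities there, 63 and 43, were below the limits from the negative control spots, 73.7 and 50.3. Each miR-369 bound, here and below, is under 0.24 on the log2 scale, the SD of the differences between PKM1 KI ES and V6.5 ES. These values therefore show no difference in miR-369. The remaining lists had medians between -0.13 and 0.13 in PKM1 KI ES, from liver, gut and pancreas (0.02 with spike scaling) to heart and skeletal muscle (-0.04 with local background), with 0.06 for miR-200, 0.05 for Dlk1-Dio3, 0.06 for the Hox cluster miRNAs, 0.00 for neural, 0.00 for blood and endothelium and -0.11 for the miR-15, miR-16, miR-195 and miR-497 family (0.08 with local background).

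**Figure D2:**
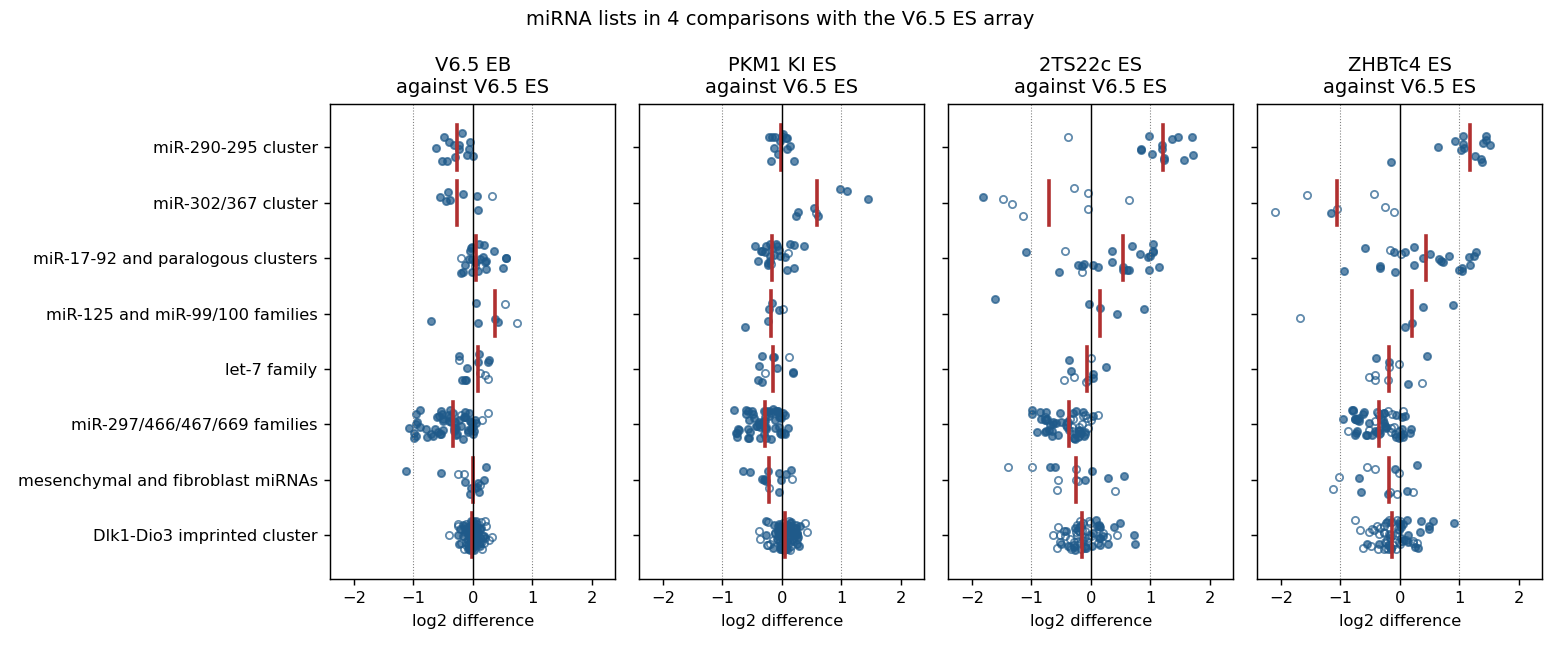
log2 difference from V6.5 ES (horizontal axis) of the detected members of 8 fixed miRNA lists (vertical axis) in the 4 comparisons; each point is 1 miRNA, filled where detected on both arrays and open where detected on 1, the red bar is the list's median and the dotted lines mark 2-fold. The miR-302 and miR-367 median lies at 0.59 in PKM1 KI ES, -0.71 in 2TS22c ES and -1.06 in ZHBTc4 ES, and the miR-290-295 median at 1.21 in 2TS22c ES and 1.18 in ZHBTc4 ES.

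2TS22c ES and V6.5 ES differed by more, with 24 miRNAs at least 2-fold higher and 16 at least 2-fold lower in 2TS22c among 804. The miR-290-295 cluster was higher: 10 of its 14 members passed 2-fold, led by miR-292-3p at 3.30-fold, miR-293-3p at 3.26-fold and miR-295-3p at 2.96-fold, with miR-294-3p at 2.57-fold, and the median was 1.21, above all matched lists. The related miR-17-92 and paralogous clusters, which promote proliferation, had a median of 0.54 (percentile 99.995), or -0.09 with spike scaling and 0.05 with the authors' values, with miR-20a-5p 2.22-fold, miR-106b-5p 2.07-fold and miR-17-5p 2.07-fold higher. A total of 7 of the list's 24 detected members were lower, among them miR-92b-5p by 2.14-fold. The list holds miR-92b-5p although it is not part of these clusters. In the opposite direction, miR-302d-3p was lower, with its 2TS22c spot at the detection limit (raw intensity 60, limit 59.9, against 342 on V6.5 ES), and miR-302a-3p and miR-302b-3p were detected on V6.5 ES only, at least 2.34-fold and at least 2.21-fold above 2TS22c; the cluster's median was -0.71 (-0.51 with bounds), below all matched lists. With local background correction that median was -0.24, and the log2 differences of miR-302d-3p, miR-302b-3p and miR-302a-3p were -0.38, -0.46 and -1.50. miR-125b-5p was also lower, again to the detection limit (61, against 303 on V6.5 ES).

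Among single miRNAs outside these clusters, miR-3096b-5p was 9.69-fold higher in 2TS22c than in V6.5 ES, at a log2 signal of 10.83 against 6.98 to 8.04 on the other 4 arrays. miR-1195 (3.06-fold), miR-182-5p (2.78-fold) and miR-3963 (2.39-fold) were also higher, miR-3963 by only 0.14 on the log2 scale with spike scaling. The lowest was miR-1892, by 4.72-fold, followed by miR-2137 (2.85-fold), miR-711 (2.83-fold), miR-6538 (2.71-fold), miR-2861 (2.50-fold), miR-326-5p (2.44-fold) and miR-762 (2.41-fold). In all, 297 miRNAs were detected on V6.5 ES and not on 2TS22c, against 50 the other way. Among the brightest of the latter were miR-744-3p (at least 1.81-fold) and miR-322-5p (at least 1.53-fold). The detection limit was passed by 11 of 24 negative control spots on V6.5 ES and by 3 on 2TS22c. The 297 and 50 are therefore no count of miRNAs lost or gained. With the limit from the negative control spots, 472 miRNAs were detected on V6.5 ES and 387 on 2TS22c.

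Several other lists also differed. Mesenchymal and fibroblast miRNAs had a median of -0.25 in 2TS22c (percentile 2.78), and 7 of 14 were detected on V6.5 ES only, miR-29a-3p at least 1.94-fold and miR-199a-3p/miR-199b-3p at least 1.93-fold above 2TS22c. Across the processings the log2 difference of miR-199a-3p/miR-199b-3p ranged from -3.85 to -0.77. Against PKM1 KI ES in place of V6.5 ES the list's median was -0.02. The miR-297, miR-466, miR-467 and miR-669 families had a median of -0.36 below all matched lists, or -0.28 with bounds. The Dlk1-Dio3 cluster had a median of -0.15 (percentile 0.89), but 40 of its 68 members were detected on V6.5 ES only and with bounds the median was 0.00. Scaled to the median of the miRNAs on all arrays it was 0.02. Other list medians lay between -0.20 for miR-34 and 0.20 for miR-15, miR-16, miR-195 and miR-497, with -0.07 for let-7, 0.16 for miR-125 and miR-99/100, 0.01 for miR-200, 0.07 for heart and skeletal muscle, -0.05 for neural, 0.12 for liver, gut and pancreas, -0.03 for blood and endothelium, 0.05 for Hox, 0.13 for miR-322 and miR-503 and -0.17 for the miRNAs acting on pyruvate kinase M. Each had a percentile from 13.0 to 96.4. Apart from miR-34, each of these lists had the other sign under at least 1 other processing. Of the 4 detected miR-34 members, 3 were seen on V6.5 ES only, and with bounds the miR-34 median was -0.02. With spike scaling miR-125 and miR-99/100 lay at -0.14, miR-322 and miR-503 at -0.09, miR-15, miR-16, miR-195 and miR-497 at -0.03, liver, gut and pancreas at -0.11, Hox at -0.09, miR-200 at -0.13 and heart and skeletal muscle at -0.01. With median scaling let-7 lay at 0.11, neural at 0.15, blood and endothelium at 0.18 and pyruvate kinase M at 0.02. Other processings moved some of these lists further. Against V6.5 ES and without bounds, medians ranged from -1.46 to 0.11 for let-7 and from -1.66 to -0.01 for miR-34. They ranged from -0.78 to 0.02 for pyruvate kinase M and from -0.67 to 0.22 for miR-125 and miR-99/100. For heart and skeletal muscle the range was -0.60 to 0.26. miR-369-3p was again seen on V6.5 ES only, at least 1.01-fold above 2TS22c.

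ZHBTc4 ES gave a like picture against V6.5 ES, with 21 miRNAs at least 2-fold higher and 13 at least 2-fold lower among 805. In the miR-290-295 cluster 11 of 14 members passed 2-fold, with miR-291a-3p 2.85-fold, miR-292-3p 2.73-fold and miR-294-3p 2.57-fold higher, and the median was 1.18, above all matched lists. miR-20a-5p (2.43-fold), miR-106b-5p (2.37-fold) and miR-18a-5p (2.27-fold) were among the 6 members of the miR-17-92 and paralogous clusters past 2-fold, and that list's median was 0.45 (percentile 99.95), or 0.01 with spike scaling and 0.09 with the authors' values, with 7 of 24 members lower. All 7 detected members of the miR-302 and miR-367 cluster were lower, with a median of -1.06 (-0.86 with bounds) below all matched lists, but only -0.15 with local background correction. miR-302d-3p was at least 3.57-fold and miR-302a-3p at least 2.36-fold lower than on V6.5 ES. miR-302b-3p was lower to the detection limit (raw intensity 62, limit 61.6, against 218 on V6.5 ES), and miR-125b-5p was at least 3.16-fold lower. With local background correction the log2 differences of miR-302d-3p and miR-302b-3p were -0.15 and -0.17, while that of miR-302a-3p was -1.46.

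Single miRNAs outside these clusters included miR-1195, 3.06-fold higher, miR-3963, 2.39-fold higher, and miR-1892, 4.06-fold lower. miR-2137, miR-711, miR-328-5p and miR-326-5p were 2.85-fold, 2.69-fold, 2.50-fold and 2.41-fold lower. The folds of miR-1195, miR-3963, miR-2137 and miR-294-3p equal those in 2TS22c because quantile normalization gives spots of equal rank one value. Their equality is no measure of agreement: miR-2137 had raw intensities of 2401 on 2TS22c and 2990 on ZHBTc4. Detection was on V6.5 ES only for 285 miRNAs and on ZHBTc4 only for 51. Here too the limit was passed by more negative control spots on V6.5 ES (11 of 24) than on ZHBTc4 (2). Mesenchymal and fibroblast miRNAs had a median of -0.18 (percentile 1.95), with miR-29a-3p at least 1.96-fold and miR-199a-3p/miR-199b-3p at least 1.95-fold lower. Across the processings the log2 difference of miR-199a-3p/miR-199b-3p ranged from -3.37 to -0.34. Against PKM1 KI ES the list's median was -0.03. The miR-297, miR-466, miR-467 and miR-669 median was -0.35, below all matched lists, or -0.27 with bounds, that of let-7 was -0.19 (percentile 2.48), or -0.06 with bounds, and that of Dlk1-Dio3 was -0.13 (percentile 0.22), or 0.00 with bounds. The other lists had medians of 0.20 for miR-125 and miR-99/100, 0.01 for miR-200, 0.00 for heart and skeletal muscle, -0.12 for neural, 0.13 for liver, gut and pancreas, -0.12 for blood and endothelium, -0.08 for Hox, 0.17 for miR-322 and miR-503, 0.12 for miR-15, miR-16, miR-195 and miR-497, -0.13 for miR-34 and -0.02 for the miRNAs acting on pyruvate kinase M. Spike scaling turned the sign for miR-200 (-0.13), liver, gut and pancreas (-0.08), miR-322 and miR-503 (-0.06) and miR-15, miR-16, miR-195 and miR-497 (-0.11). Median scaling turned it for neural (0.01), Hox (0.03) and pyruvate kinase M (0.06), and local background for blood and endothelium (0.04). The miR-125 and miR-99/100 families lay at -0.00 with spike scaling. Other processings gave larger differences. Against V6.5 ES and without bounds, medians ranged from -1.60 to -0.07 for let-7 and from -0.84 to -0.01 for miR-34. The mesenchymal and fibroblast median ranged from -1.19 to -0.17. miR-369-3p was at least 1.02-fold lower.

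These counts depend on the scaling. With the arrays scaled to the spike controls, the miRNAs detected on both arrays shifted by -0.23 in 2TS22c and by -0.21 in ZHBTc4, and the counts higher and lower became 1 and 88 in 2TS22c and 0 and 82 in ZHBTc4. The miR-290-295 median was then 0.39 in 2TS22c and 0.48 in ZHBTc4, still positive, the miR-302 and miR-367 median -0.85 and -1.25, and the miR-17-92 median -0.09 and 0.01. Scaled to the median of the miRNAs on all arrays, the shift was 0.17 in 2TS22c and the counts were 15 and 21 there and 8 and 22 in ZHBTc4; scaled to the 75th percentile, they were 10 and 40, and 7 and 26. With the authors' values the shift was -0.58 in 2TS22c and -0.45 in ZHBTc4, and the counts were 37 and 275, and 32 and 237. Under spike, median and 75th percentile scaling the counts in the EB were 21 and 1, 1 and 7, and 1 and 5, and in PKM1 KI ES 3 and 1, 3 and 1, and 2 and 1.

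The differences of 2TS22c ES and ZHBTc4 ES from V6.5 ES went together across the 392 miRNAs on all arrays, with r of 0.917 and a covariance of 0.31. Because both are taken from the same V6.5 ES array, unchanged arrays would give r of 0.50 and a covariance of 0.03 in simulation. With no array shared, using PKM1 KI ES as the reference for one of the 2 lines, r was 0.842 and 0.844 and the covariance 0.316 and 0.320. Of the miRNAs at least 2-fold higher, 18 were the same in both lines, and of those lower 13, among 768 miRNAs. Simulated unchanged arrays that share V6.5 ES gave 0 in both directions. They held 392 miRNAs with normally distributed differences of SD 0.24, where a 2-fold difference hardly occurs. That 0 is therefore no measure for the overlap. ZHBTc4 ES was alone on its chip, but 2TS22c ES, which shared a chip with V6.5 ES, showed the same differences.

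**Figure D3:**
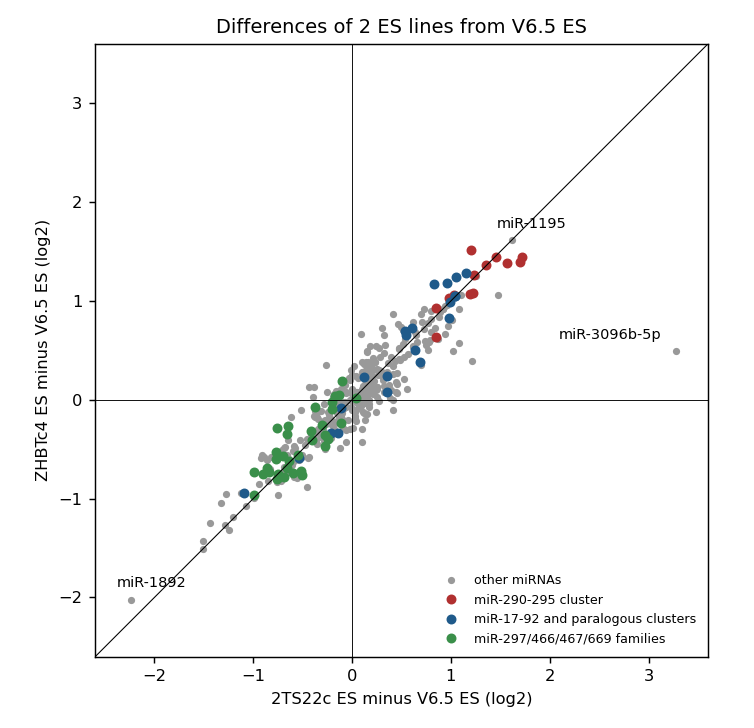
log2 difference from V6.5 ES of the 400 miRNAs detected on V6.5 ES, 2TS22c ES and ZHBTc4 ES, in 2TS22c (horizontal axis) against ZHBTc4 (vertical axis); each point is 1 miRNA, 3 lists are coloured and the diagonal marks equal differences. Most points follow the diagonal, and miR-3096b-5p lies off it, at 3.28 in 2TS22c.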

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

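Every test weighed in this part was chosen after the result had been seen, and the first form of the cross-hybridization test was replaced after it had been run, with the same outcome. The first pattern is that 2TS22c ES and ZHBTc4 ES differed from V6.5 ES in the same miRNAs. The chip is argued against as the cause, since 2TS22c and V6.5 ES lay on one chip and were at least 2-fold apart in 40 miRNAs, while 2TS22c and ZHBTc4 lay on different chips and were apart in 1. Less labelled RNA on the 2 arrays cannot be the whole cause, because it lowers every miRNA, and the miR-290-295 cluster was higher even when scaled to the spike controls, by a median of 0.39 in 2TS22c (13 of 14 members) and 0.48 in ZHBTc4 (12 of 14), beside -0.20 and -0.18 for all detected miRNAs. Unspecific binding on the V6.5 ES array stays open for the miRNAs at least 2-fold lower, where a test on the raw intensity they lost was dropped because the 2-fold limit fixes its outcome. It also stays open for the lower number of detected miRNAs, since the ratio of V6.5 ES over the line dropped from 1.49 to 1.22 in 2TS22c and from 1.45 to 1.29 in ZHBTc4 when the negative control spots set the limit; the genetic difference between the lines and fragments of other RNAs that bind to some probes were not tested.

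The second pattern is that mesenchymal and fibroblast miRNAs were lower in 2TS22c and ZHBTc4 than on V6.5 ES. A candidate explanation is RNA of feeder fibroblasts in the V6.5 ES culture, which the labels neither state nor exclude. Of the 9 list members with a V6.5 ES intensity of at least 1.5 times the detection limit, 7 were lower in both lines, among them miR-21a-5p, with raw intensities of 316 on V6.5 ES, 117 on 2TS22c and 119 on ZHBTc4. The other 2 were higher, miR-22-3p by 0.30 and 0.29 and miR-143-5p by 0.55 and 0.11, so the test decides neither way, and ES cells can express members of this list themselves. The choice of members by their V6.5 ES intensity also favours lower values on other arrays. In PKM1 KI ES 7 of the 9 were lower than on V6.5 ES as well. Against PKM1 KI ES the list's median was -0.02 and -0.03, with members on both sides, and 6 of the 9 were lower in both lines, among them miR-21a-5p by -0.56 and -0.61, miR-29a-3p by -0.73 and -0.86 and miR-199a-3p/miR-199b-3p by -0.74 and -0.37.

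The third pattern is the higher miR-302 and miR-367 cluster in PKM1 KI ES. Cross-hybridization between the near-identical miR-302 3p arms as the whole cause is argued against by the other 4 detected members. These, the 5p arms and miR-367-3p, were all higher, with a median of 0.40 at percentile 99.98 of matched random lists. This support is limited, since miR-302d-5p was detected on the PKM1 KI array only. A rise of the whole cluster would also lift these members whether or not the 3p probes share signal. How far the 3p arms share signal therefore stays open, and sharing among the 5p arms was not tested. Only 8 of the cluster's 10 spots were detected on either array and could enter. A lower share of non-ES cells on that array would raise the markers of ES cells alike, and as the cause of this pattern it is argued against by the miR-290-295 cluster, whose median log2 difference was -0.0179, against 0.59 for miR-302 and miR-367. Lists of differentiated cells went both ways there. Mesenchymal and fibroblast miRNAs (-0.22, or from -0.67 to 0.03 across the processings) and let-7 (-0.15, or from -0.82 to 0.02) were lower. So were liver, gut and pancreas (-0.13, or from -0.17 to 0.02) and the miR-125 and miR-99/100 families (-0.19). Neural (0.00), blood and endothelium (0.00), Hox (0.06) and heart and skeletal muscle (0.13, or -0.04 with local background) were not. For the lower lists a lower share of non-ES cells stays open. The cluster also differed from V6.5 ES in 2TS22c and ZHBTc4, ES lines not labelled with the knock-in. Its median there was -0.71 and -1.06, or -0.24 and -0.15 with local background correction. What remains open is that the pattern rests on 1 array. The knock-in, the clone or the state of the culture may each differ from V6.5 ES. A difference in the miR-302 and miR-367 cluster tied to the knock-in is a hypothesis that these data cannot separate from the others.

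Among the 25 array measures and list means compared over the 4 ES arrays, 1 had a single array far from the others: the mean log2 signal of the miR-322 and miR-503 cluster was 6.28 on V6.5 ES and 6.39 to 6.41 on the other 3. Among the 100 named miRNAs, 2 did so: miR-1949 was lower on PKM1 KI ES by 0.28 than the median of the others (a difference of -0.28), which the rule picks whatever its size because quantile normalization gave the other 3 arrays the same value, and miR-694 was higher on V6.5 ES by 0.46. For 4 arrays drawn alike, chance alone gives about 1 in 20. That rate cannot be applied here, since the 4 ES arrays fell into 2 pairs and the named miRNAs were chosen by their differences. The number flagged therefore decides nothing. The negative control spots, which enter no main comparison, lay above the detection limit for 11 of 24 spots on V6.5 ES, 16 on PKM1 KI ES, 12 on the EB, 3 on 2TS22c and 2 on ZHBTc4.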

How the results depend on the processing

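The alternatives called added below were chosen after the result had been seen. The limma test gave 0 miRNAs in both directions under 15 of its 16 alternatives, including without each ES line in turn (0 to 0 higher and 0 to 0 lower; leaving out ZHBTc4 ES is also the alternative without the second chip). With an intensity trend 1 miRNA was lower in the EB, miR-6366 by -0.36, whose ES values do not differ because it ranked the same on all 4 arrays. The number of miRNAs at an unadjusted p under 0.05 in the limma test moved too, most with spike scaling, where all of them were higher in the EB. Counts of miRNAs at least 2-fold apart moved more than the limma calls. An offset of 16 gave 6 higher and 11 lower in the EB, 2 lower in PKM1 KI ES, 44 and 30 in 2TS22c and 21 lower in ZHBTc4. No background correction gave 2 and 9 in the EB, and normalization of only the 2 arrays 2 and 6. Median scaling gave 7 lower in the EB, 15 higher in 2TS22c, and 8 and 22 in ZHBTc4; 75th percentile scaling gave 5 lower in the EB, 10 and 40 in 2TS22c and 7 and 26 in ZHBTc4. The authors' values, which have no offset, gave 35 and 98 in the EB, 46 and 49 in PKM1 KI ES, 37 and 275 in 2TS22c and 32 and 237 in ZHBTc4. Of the alternatives added after seeing the data, local background gave 9 and 11 in the EB and 8 and 3 in PKM1 KI ES, spike control scaling 21 and 1 in the EB, 1 and 88 in 2TS22c and 0 and 82 in ZHBTc4, and the negative control limit 1 lower in the EB. Apart from the smaller offset, whose construction widens the folds of dim miRNAs, the cause was not tested. The other counts stayed within 1.5 times the main ones. No list median of at least 1 on the log2 scale and no named miRNA at least 2-fold apart changed sign; 540 of the list medians moved by less than the spread of their members and 72 by more, and 838 values of single miRNAs moved by less than 0.24 and 418 by more. No paired analysis was possible because each group has 1 array. Dim miRNAs limit what can be seen: the median intensity of the detected miRNAs was 60 to 82 against blank means of 33.2 to 49.7.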

Other observations

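These comparisons were chosen after the values had been seen. The Sfmbt2 group of miRNAs was lower on each of the other 4 arrays than on V6.5 ES, with list medians of -0.33 in the EB, -0.29 in PKM1 KI ES, -0.36 in 2TS22c and -0.35 in ZHBTc4. Since all 4 share the V6.5 ES array, this describes 1 array as much as 4. The median of 2TS22c against PKM1 KI ES was -0.13 and that of ZHBTc4 against PKM1 KI ES -0.08.

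Only 4 miRNAs lay at least 2-fold above all of the other 4 arrays on a single one: miR-302a-3p and miR-302d-3p on PKM1 KI ES, miR-711 on the EB, and miR-3096b-5p on 2TS22c, by 2.79 on the log2 scale. None lay at least 2-fold below all of the others. miR-706, the lowest miRNA of PKM1 KI ES, had log2 signals of 8.69 on V6.5 ES, 7.20 on PKM1 KI ES, 7.96 on the EB, 9.48 on 2TS22c and 9.50 on ZHBTc4.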
